A study of Arabidopsis thaliana with 16 samples.

How the data were processed

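Gene expression was measured by RNA sequencing in leaves of Arabidopsis thaliana, of the accession Col-0 and of the nac53-1 78-1 double mutant, each 24 h after a mock infiltration or an infiltration with Pseudomonas syringae pv. tomato DC3000 (Pst). The labels describe 16 samples in 4 groups, total RNA isolated with an RNeasy Mini Kit, and processing with FastQC and kallisto on the build TAIR10, without versions. The deposited table of the authors held expected counts, which are the counts that kallisto estimates for each transcript model, with 1 model per locus for 27416 loci and no scaling to depth. Of all values, 4.56% were not whole at a tolerance of 1e-06, and 2475 loci had such a value in at least 1 library. A gene whose estimates were not whole may share reads with a similar locus.

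The table had 16 columns, and 13 were used. The names of 6 columns matched a sample, which gave Col-0 mock 1 to 4 and Col-0 Pst 1 and 2. The names of 7 columns matched a group but not a single sample, and these libraries carry letters (Col-0 Pst a, mutant mock a to c and mutant Pst a to c). The names of 3 columns pointed to different groups or to no single group and were not used here. The groups thus held 4, 3, 3 and 3 libraries. The labels name no batch and do not say that replicates came from separate plants, so p-values measure the spread between samples, which may be partly technical.

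Estimated counts were rounded to whole numbers. Totals per library were 22420373 to 24329063 in Col-0 mock, 14461502 to 24665839 in Col-0 Pst, 19933090 to 26100206 in mutant mock and 22327490 to 23613387 in mutant Pst. Organelle loci held 0.838% to 1.244% of the counts. The limit that 0 counts allows was taken as 3 counts of the total, which is 0.115 to 0.207 CPM, and these limits and the counting intervals cover counting error only. Correlations and principal components used log2 CPM with a prior count of 2. Reference annotation of the build TAIR10.1 was used only for gene names and for neighbouring genes.

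Differences were tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, two-sided) in 1 model with a mean per group and TMM factors. The function filterByExpr kept 19680 genes with 99.972% of the counts and left out 7736. Comparisons were Pst against mock in each genotype, mutant against Col-0 in each treatment, and the interaction, which is the mutant response minus the Col-0 response. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and genes with an adjusted p under 0.05 were called. A total least squares slope of the mutant on the Col-0 log2 response was computed across genes, with a jackknife standard error over libraries.

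Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 23 lists of a comparison, beside camera with an estimated correlation and fry. No list call held with an estimated correlation. The 17 pathway lists covered 26S proteasome subunits, proteasome activators with CDC48 and ubiquitin, salicylic acid, pattern-triggered immunity, jasmonate, abscisic acid, ethylene, camalexin and indole glucosinolates, aliphatic glucosinolates, photosynthetic light reactions, the Calvin cycle, chlorophyll synthesis, endoplasmic reticulum chaperones, the heat shock response, autophagy, leaf senescence, and respiratory burst with mitochondrial stress. The 6 other lists held markers of epidermis, guard cells, phloem, xylem and dividing cells, and clock genes. Of 464 members written, 428 were used and 36 were left out because the reference did not link symbol and locus to a gene of the table. Among the latter, PAB2 and NAS2 were left out because the reference gives the symbol to another gene, where the rule written beforehand would have used that other gene.

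Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, for 16 libraries. The rule named NAC53 and NAC78 first. In each pairwise comparison it named the 6 called genes with the largest rise and the 6 with the largest fall that reached a mean of 10 CPM in the higher group with no overlap between the libraries, and PR1, EDS16 (ICS1) and FRK1. It also named the 2 members with the smallest p of each called pathway list, and for the interaction the 8 largest positive and the 8 largest negative values. The report prints a selection of the genes so named.

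Alternatives were DESeq2 1.42.0, limma voom, RLE and upper quartile factors, no filter and a stricter filter on low counts, organelle loci left out, only the groups compared, a replicate block, each library left out, an adjusted p under 0.01, a fold of 1.5 tested with glmTreat, and for the slope only genes with a mean of at least 10 CPM. After seeing the data, 4 were added, which were library totals without factors, loci with fractional estimates left out, list members as written, and the mock library of each genotype nearest the Pst libraries on the first principal component left out.

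The tests were tested on simulated data with changes of known size. Few genes were changed, 66 or 67 at each fold and a list of 38, of 19328 to 19364 in the fit. In the data 81.3% of genes were called in Col-0, 69% in the mutant, 24.7% between genotypes after Pst and 12% for the interaction. Recovery and false calls depend on this share, so the percentages below hold for sparse changes only. At a 2-fold change the percentage of changed genes recovered was 40.3 in each response, 46.3 between genotypes in mock, 35.8 between genotypes after Pst and 5.97 for the interaction. At a 4-fold change it was 89.4 in Col-0, 80.3 in the mutant, 90.9 between genotypes in each treatment and 56.1 for the interaction. False calls were 1.14% to 4.65% of the genes called. The slope was simulated separately, with every gene changed and each mutant log2 change exactly 0.7 of that in Col-0, and was fitted as 0.701. In the data genes deviate from a common ratio, so this does not show how accurate the slope is for them.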

Results

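RNA was sequenced from leaves of 5-week-old Arabidopsis thaliana plants 24 h after infiltration. The plants were the wild-type accession Col-0 and nac53-1 78-1, a double mutant of the transcription factor genes NAC53 and NAC78. Each genotype received either a mock solution of 10 mM MgCl2 or the same solution with the bacterial leaf pathogen Pseudomonas syringae pv. tomato DC3000 (Pst) at an OD600 of 0.2. The 13 libraries compared were 4 of Col-0 mock, 3 of Col-0 Pst, 3 of mutant mock and 3 of mutant Pst. Estimated counts summed to between 14461502 and 26100206 per library, and 0 counts in a library allowed a level of up to 0.115 to 0.207 CPM (counts scaled to the library total). Values are given as mean ± SD in CPM, with n = 4 for Col-0 mock and n = 3 for each other group. The standard error (SE) of a log2 fold change is its absolute size divided by the square root of its F statistic. It was thus derived from the test and may be too small where counts are few. The question of the series was how the immune response to the bacterium differs between the genotypes.

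Infection separated the libraries more than the genotype did. The first principal component held 84.7% of the variance and placed all 7 mock libraries below 0 and all 6 Pst libraries above 0. The 3 mutant Pst libraries lay between 67.88 and 104.7 on it, and the 3 Col-0 Pst libraries between 167.3 and 201. The mock libraries nearest the Pst side were mutant mock c at -73.31 and Col-0 mock 4 at -100.5. The 10 most abundant loci held 8.92% to 11.59% of the counts in mock libraries and 4.44% to 5.27% in Pst libraries. Correlations of log2 CPM between libraries of 1 group ranged from 0.952 to 0.987.

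**Figure D1:**
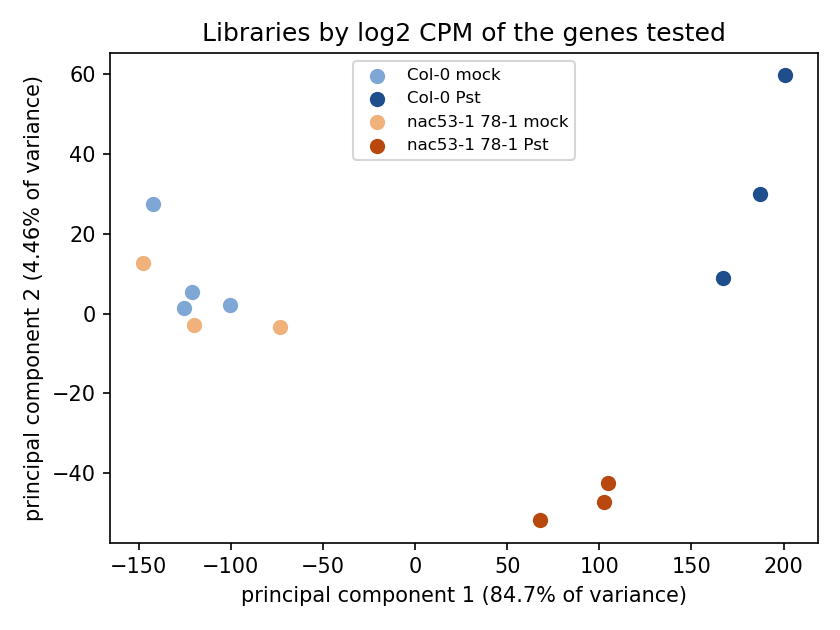
Each point is 1 library of either genotype after mock or Pst treatment, placed by its scores on principal components 1 (84.7% of the variance, x axis) and 2 (4.46%, y axis) of log2 CPM, with colour for the group. The mutant Pst libraries, at 67.88 to 104.7 on the x axis, lie between the mock libraries and the Col-0 Pst libraries.

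The targeted genes matched the genotype labels in all 13 libraries. NAC53 (AT3G10500) and NAC78 (AT5G04410) encode NAC transcription factors known as regulators of proteasome genes. In Col-0, NAC53 rose from 21.4 ± 7.01 CPM in mock to 215 ± 12.1 CPM after Pst (log2 3.33, SE 0.23, adjusted p = 6.47e-08). NAC78 rose from 114 ± 14.3 to 605 ± 105 CPM (log2 2.41, SE 0.18, adjusted p = 1.03e-07). In the mutant, NAC53 was at 1.69 ± 0.445 CPM in mock and 12 ± 2.51 CPM after Pst. NAC78 was at 2.68 ± 0.776 and 8.72 ± 0.25 CPM. Both were lower in the mutant in mock, NAC53 by 12.5-fold and NAC78 by 42.0-fold, and after Pst, NAC53 by 17.9-fold and NAC78 by 69.3-fold. The remaining signal still rose with Pst in the mutant (log2 2.81 for NAC53, adjusted p = 4.49e-06, and 1.69 for NAC78, adjusted p = 2.3e-05). The interaction terms of both genes did not pass the threshold (NAC53 adjusted p = 0.349, NAC78 adjusted p = 0.105). That of NAC78 passed it with DESeq2 (adjusted p = 0.0428) and without Col-0 Pst 1 (0.0497), in a range up to 0.305 over the alternatives.

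**Figure D2:**
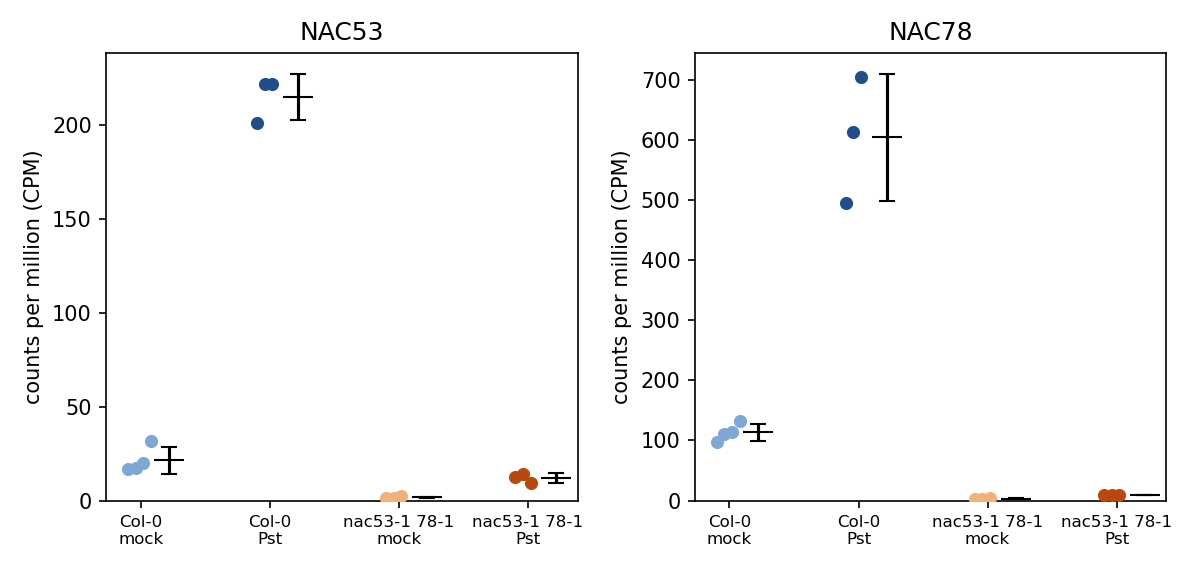
Points show the CPM of NAC53 (left) and NAC78 (right) in each library, by genotype and treatment, and the black bars give the group mean and SD (n = 4 for Col-0 mock, n = 3 otherwise). Pst raised NAC53 to 215 ± 12.1 CPM and NAC78 to 605 ± 105 CPM in Col-0, and every mutant group mean lies at or below 12 CPM.

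The first comparison asked how wild-type leaves responded to Pst. In Col-0, genes of photosynthesis fell together, and genes of protein turnover, jasmonate and ethylene rose. All 47 nuclear genes of the photosynthetic light reactions fell, with a median log2 change of -4.44. LHCA3, a light-harvesting protein of photosystem I, fell 21.8-fold from 4443 ± 257 to 204 ± 20.1 CPM. NAC53, NAC78 and 35 of the 38 subunits used in the list of the 26S proteasome, the complex that degrades ubiquitin-tagged proteins, rose. In all, 15997 of 19680 genes tested changed (81.3%), 7687 of them higher and 8310 lower after Pst.

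Photosynthesis lists moved as blocks in Col-0. Of the light reaction genes, 47 of 47 fell (camera adjusted p = 6.65e-17, and adjusted p = 0.507 with an estimated correlation). PETE1, a plastocyanin, fell 32.8-fold. All 19 Calvin cycle genes fell by a median log2 of -4.40 (camera adjusted p = 1.04e-08, and adjusted p = 0.507 with an estimated correlation). Among them, the fructose-bisphosphate aldolase FBA2 fell 21.1-fold and the chloroplast fructose-1,6-bisphosphatase HCEF1 fell 27.7-fold. All 21 genes of chlorophyll synthesis and its GLK regulators fell by a median of -3.63 (camera adjusted p = 7.55e-08, and adjusted p = 0.507 with an estimated correlation). CH1, the chlorophyll a oxygenase, fell 11.7-fold, and CRD1, a cyclase of the pathway, fell 25.4-fold from 3084 ± 283 to 121 ± 20.03 CPM. All 17 genes of aliphatic glucosinolate synthesis, a pathway of defence metabolites, fell by a median of -4.69 (camera adjusted p = 2.36e-05, and adjusted p = 0.507 with an estimated correlation). MAM1, which elongates the methionine chain, fell 37.6-fold. IMD1 of the same pathway fell 27.4-fold, but its estimates were fractional in all 13 libraries, so it may share reads with a similar locus. For these 4 lists the counts adjusted over the list alone were the same as those over all genes.

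Protein turnover genes rose in Col-0. The 35 proteasome subunits that rose, also 35 when adjusted over the list alone, gave a list median of 1.32 (camera adjusted p = 8.43e-09, and adjusted p = 0.507 with an estimated correlation). RPN10, a ubiquitin receptor of the proteasome, rose 4.54-fold from 72.3 ± 9.03 to 328 ± 32.3 CPM, and the receptor RPN13 rose 3.98-fold. Of 10 genes for proteasome activators, CDC48 and ubiquitin, 9 rose (camera adjusted p = 0.00265, and adjusted p = 0.507 with an estimated correlation), among them UFD1, a partner of CDC48, by 2.34-fold. That list call also ended when loci with fractional estimates were left out (adjusted p = 0.341). In the autophagy list, 18 of 20 genes rose with a median of 2.57 (camera adjusted p = 1.27e-06, and adjusted p = 0.507 with an estimated correlation). The ubiquitin-like autophagy proteins ATG8D and ATG8I (named APG8H in the reference) rose 9.7-fold and 5.67-fold. In the endoplasmic reticulum chaperone list, 14 of 16 members fell by a list median of -2.17 (camera adjusted p = 0.0139, and adjusted p = 0.587 with an estimated correlation). The members that rose were BZIP28 (4.53-fold) and BZIP60 (4.78-fold), transcription factors of the unfolded protein response. The call of this list ended when loci with fractional estimates were left out (adjusted p = 0.168).

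Hormone and defence genes of Col-0 moved in both directions. Jasmonate synthesis and signalling had 22 members that rose and 2 that fell, of 30 (median 3.15, camera adjusted p = 0.000251, and adjusted p = 0.587 with an estimated correlation). LOX3, a lipoxygenase of jasmonate synthesis, rose 11.5-fold from 86.3 ± 13.2 to 990 ± 209 CPM, and the jasmonate repressor JAZ3 rose 5.35-fold. In the ethylene list, 16 of 22 rose and 1 fell (median 1.83, camera adjusted p = 0.000398, and adjusted p = 0.507 with an estimated correlation), with the chitinase HCHIB 31.8-fold and the ethylene response factor ERF1 12.4-fold higher. In the list of immunity triggered by microbial patterns, 18 of 28 rose and 6 fell (median 0.96, camera adjusted p = 0.0267, and adjusted p = 0.587 with an estimated correlation). WRKY29, a transcription factor of that pathway, rose 35.0-fold, and FRK1, a receptor-like kinase used as its marker, fell 1.72-fold (adjusted p = 0.0157). Of 27 salicylic acid genes, 14 rose and 8 fell, and 14 and 9 when adjusted over the list alone (camera adjusted p = 0.255). EDS16, also known as ICS1, which makes the salicylic acid precursor isochorismate, rose 10.8-fold, and the marker PR1 was at 49.7 ± 41.6 CPM in mock and 81.5 ± 21.3 CPM after Pst (log2 0.71, adjusted p = 0.211). Without Col-0 mock 4 the PR1 log2 change was 1.51 (adjusted p = 0.0034) and with both mock libraries nearest the Pst side left out it was 1.48 (0.00321), in a range of adjusted p from 0.00321 to 0.418 over the alternatives. Leaf senescence genes rose in 9 of 13 cases and fell in 2 (median 2.31, camera adjusted p = 0.0338, and adjusted p = 0.551 with an estimated correlation), with the regulator WRKY6 15.2-fold and the pheophytinase PPH 6.81-fold higher. Of the respiratory burst and mitochondrial stress genes, 9 of 12 rose and 2 fell (camera adjusted p = 0.0398, and adjusted p = 0.587 with an estimated correlation), among them the alternative NADH dehydrogenase NDB2 by 4.11-fold.

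Several genes went from near absence to clear expression in Col-0. AT1G11040 had 0 counts in the mock libraries and 32.7 ± 4.01 CPM after Pst, at least 256-fold higher against a floor of 3 counts per library. PGAZAT, a polygalacturonase of cell wall breakdown, rose from 0.0409 ± 0.0559 to 89.1 ± 54.8 CPM. The cytokinin oxidase CKX2 had 1 count over the 4 mock libraries and 25.3 ± 6.21 CPM after Pst, a ratio of 2290 with a counting interval of 411 to 90700. The transcription factor BHLH92 rose 731-fold. In the other direction, AT1G13650 fell 401-fold, AT2G10940 fell 282-fold, the cell wall enzyme XTH31 fell 215-fold and GA3OX1, an enzyme of gibberellin synthesis, fell 185-fold. The call of FRK1 in Col-0 ended without Col-0 Pst a (adjusted p = 0.101, in a range from 0.006 to 0.101 over the libraries left out) and without Col-0 mock 4 (adjusted p = 0.0556). The senescence call ended without Col-0 Pst 1 (adjusted p = 0.0512) and the mitochondrial stress call without Col-0 mock 1 (adjusted p = 0.0623), with the stricter filter on low counts (0.0507) and with only the groups compared (0.0616).

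The second comparison asked how the double mutant responded to Pst. Photosynthesis genes fell and jasmonate, ethylene and autophagy genes rose in nac53-1 78-1 as well. Proteasome subunits went both ways: 19 of 38 rose and 4 fell, with a list median of 0.35. LHCA3 fell 4.38-fold, from 4278 ± 909 to 977 ± 281 CPM. In total, 13588 of 19680 genes changed (69%), 6606 higher and 6982 lower.

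All 47 light reaction genes fell in the mutant (median -2.00, camera adjusted p = 1.63e-12, and adjusted p = 0.533 with an estimated correlation), and the photosystem I subunit PSAH-1 fell 3.6-fold. All 19 Calvin cycle genes fell (median -2.16, camera adjusted p = 3.34e-07, and adjusted p = 0.533 with an estimated correlation), FBA2 by 4.4-fold and the regulator CP12-1 by 2.21-fold. All 21 chlorophyll genes fell (camera adjusted p = 3.34e-07, and adjusted p = 0.533 with an estimated correlation), CH1 by 3.67-fold and GSA1, an enzyme of 5-aminolevulinate synthesis, by 2.47-fold. Of the aliphatic glucosinolate genes, 13 of 17 fell (median -1.59, camera adjusted p = 0.00411, and adjusted p = 0.666 with an estimated correlation), with BCAT3, a branched-chain aminotransferase, down 2.77-fold. Autophagy genes rose in 18 of 20 cases (median 1.89, camera adjusted p = 7.12e-07, and adjusted p = 0.533 with an estimated correlation), ATG8D by 5.82-fold and ATG9 (named APG9 in the reference) by 5.85-fold. Jasmonate genes rose in 23 of 30 cases (median 2.24, camera adjusted p = 1.22e-05, and adjusted p = 0.666 with an estimated correlation), LOX3 by 7.88-fold and LOX4 by 5.43-fold. Ethylene genes rose in 15 of 22 cases and 1 fell (camera adjusted p = 0.000253, and adjusted p = 0.533 with an estimated correlation), HCHIB by 24.3-fold and ERF6 by 11.7-fold. Senescence genes rose in 8 of 13 cases and fell in 2, and 9 and 2 when adjusted over the list alone (median 2.12, camera adjusted p = 0.0209, and adjusted p = 0.657 with an estimated correlation), with the chlorophyll b reductase NYC1 7.34-fold and NYE1, which removes magnesium from chlorophyll, 4.57-fold higher.

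The proteasome subunits that rose in the mutant included RPN10 (2.3-fold) and RPN13 (2.4-fold), and the list call (camera adjusted p = 0.0286, and adjusted p = 0.697 with an estimated correlation) was 19 rose and 4 fell also when adjusted over the list alone. EDS16 rose 3.77-fold (adjusted p = 0.00097), FRK1 fell 3.37-fold (adjusted p = 0.000174) and PR1 stood at 68.8 ± 20.6 CPM in mock and 132 ± 66.3 CPM after Pst (log2 0.94, adjusted p = 0.146). PR1 passed the threshold without Col-0 mock 4 (log2 0.97, adjusted p = 0.0402) and with both mock libraries nearest the Pst side left out (log2 1.18, adjusted p = 0.0259), in a range up to 0.455 over the alternatives. PGAZAT had 0 counts in mutant mock and 94.1 ± 39.0 CPM after Pst, at least 731-fold higher against a floor of 3 counts per library, and the osmotin OSM34 was at least 89.4-fold higher. Proteasome activators with CDC48 and ubiquitin rose in 6 of 10 cases (median 0.83, camera adjusted p = 0.0209, and adjusted p = 0.666 with an estimated correlation), a call that ended with fractional loci left out (adjusted p = 0.8). GA3OX1 fell 17-fold and AT3G55240 fell 14.4-fold. The proteasome list call in the mutant response ended without mutant Pst a (adjusted p = 0.076), with upper quartile factors (adjusted p = 0.0952) and with fractional loci left out (adjusted p = 0.0628).

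Both responses shared most of their genes, and the 2 comparisons had no library in common. Of the genes tested, 6424 rose in both genotypes, against 2580 for independent lists of these sizes, and 6766 fell in both, against 2948. Opposite calls were few, with 4 genes that rose in Col-0 and fell in the mutant and 2 that fell in Col-0 and rose in the mutant. Across genes, which are not independent replicates, the log2 responses had a Pearson r of 0.931. The total least squares slope of the mutant response on the Col-0 response was 0.689 (jackknife SE 0.096 over libraries), and it was 0.643 to 0.779 with 1 library left out.

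**Figure D3:**
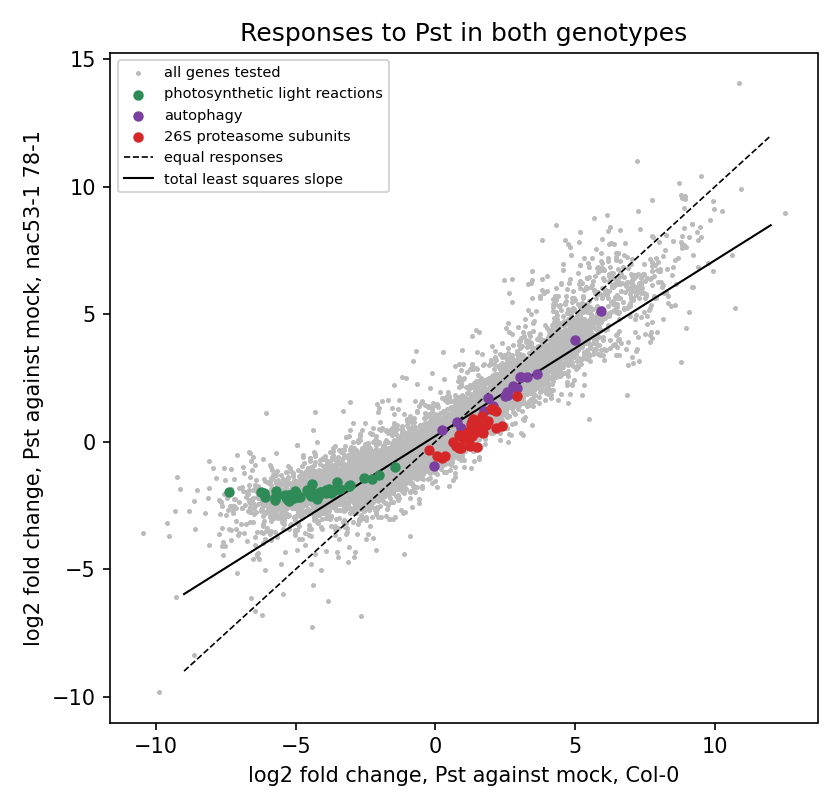
Each grey point is 1 of the 19680 genes tested, with its log2 fold change for Pst against mock in Col-0 (x axis) and in nac53-1 78-1 (y axis), and colours mark 3 gene lists. The solid line is the total least squares slope of 0.689 and the dashed line marks equal responses. Light reaction genes (green) lie above the dashed line and proteasome subunits (red) below it. Most genes that fell or rose share these sides, since 92% of the genes called in Col-0 had a smaller response in the mutant. Calling genes with the same Col-0 libraries by itself favours this, so the share may be overstated.

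The third comparison asked what the double mutant changed without bacteria. In mock leaves, edgeR called 5 genes lower in nac53-1 78-1 and 0 higher. Besides NAC78 and NAC53, these were AT2G48160, MRD1 (AT1G53480) and AT1G21670. AT2G48160 was 582-fold lower, at 0.142 ± 0.0293 CPM in the mutant and 84.5 ± 4.14 CPM in Col-0 (log2 -9.19, SE 0.33, adjusted p = 1.8e-08). MRD1 was 134-fold lower, at 0.12 ± 0.0869 against 15.8 ± 2.45 CPM (log2 -7.06, SE 0.36, adjusted p = 5.64e-06). The mutant levels of AT2G48160 and MRD1 lie near the limit that 0 counts allows (0.115 to 0.207 CPM), so their folds are approximate. AT1G21670 was 3.38-fold lower, at 14.1 ± 2.25 against 47.9 ± 9.25 CPM (log2 -1.76, SE 0.22, adjusted p = 0.00999).

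No proteasome subunit passed the threshold over all genes in mock, but 16 of 38 were lower when adjusted over the list alone. The list median was -0.30 (camera adjusted p = 2.33e-21, and adjusted p = 0.615 with an estimated correlation). With fry the adjusted p was 0.447, and no other list called in mock passed the threshold with fry (adjusted p from 0.853 to 0.966). RPT5B, an ATPase of the proteasome base, was at 8.47 ± 1.76 CPM in the mutant and 21.6 ± 5.43 CPM in Col-0 (adjusted p = 0.132), and the core subunit PBB2 at 16.5 ± 0.934 and 32.1 ± 7.29 CPM (adjusted p = 0.132). Both passed the threshold with DESeq2 (adjusted p = 4.24e-05 for RPT5B and 0.000314 for PBB2) and without mutant mock a (0.0355 and 0.0494), and PBB2 also without Col-0 mock 1 (0.0249), in ranges up to 0.995 and 0.997 over the alternatives. The light reaction genes had a median of -0.01, with 0 of 47 called by edgeR (camera adjusted p = 0.967), and the median ranged from -0.031 to 0.000272 under the other scalings. Salicylic acid genes had a median of 0.49 (camera adjusted p = 4.81e-08, and adjusted p = 0.615 with an estimated correlation) and jasmonate genes one of 0.48 (camera adjusted p = 0.000514, and adjusted p = 0.882 with an estimated correlation), each with 0 members called also when adjusted over the list alone. The tyrosine aminotransferase TAT3 was at 1451 ± 994 CPM in mutant mock and 655 ± 235 CPM in Col-0 mock, and EDS16 at 151 ± 97.0 and 80.6 ± 26.7 CPM (adjusted p = 1 for both). Without mutant mock a, TAT3 had an adjusted p of 0.0432. These lists moved with mutant mock c, the mock library nearest the Pst side at -73.31 on the first principal component, and without it the adjusted p was 0.262 for salicylic acid and 0.977 for jasmonate. Without mutant mock b the jasmonate adjusted p was 0.351, and with both mock libraries nearest the Pst side left out it was 0.536. Aliphatic glucosinolate genes had a median of -0.42 (camera adjusted p = 1.04e-06, and adjusted p = 0.615 with an estimated correlation), and 0.133 was the adjusted p without mutant mock c.

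In mock, 6 further lists passed the camera threshold, 4 of them markers of cell types, each with 0 members called also when adjusted over the list alone. Xylem markers had a median of 0.24 (camera adjusted p = 0.000514, and adjusted p = 0.615 with an estimated correlation). Guard cell markers had one of -0.33 (camera adjusted p = 0.00768, and adjusted p = 0.615 with an estimated correlation), a call that ended without mutant mock b (adjusted p = 0.149). Epidermis markers had one of -0.29 (camera adjusted p = 0.0387, and adjusted p = 0.882 with an estimated correlation). That call ended without Col-0 mock 1, 2 or 3 and without mutant mock b or c (adjusted p up to 0.387), with the stricter filter (0.0531) and with both mock libraries nearest the Pst side left out (0.121). Dividing cell markers had one of 0.24 (camera adjusted p = 0.0387, and adjusted p = 0.69 with an estimated correlation). That call ended without Col-0 mock 4 and without mutant mock a or b (adjusted p up to 0.992), with the stricter filter (0.283) and with only the groups compared (0.0544). Clock genes had a median of -0.19 (camera adjusted p = 0.0387, and adjusted p = 0.615 with an estimated correlation). That call ended without Col-0 mock 2 and without mutant mock a or b (adjusted p up to 0.302), with fractional loci left out (0.0655) and with only the groups compared (0.0545). Pattern-triggered immunity had one of 0.11 (camera adjusted p = 0.0288, and adjusted p = 0.882 with an estimated correlation). That call ended without Col-0 mock 1 or 2 and without mutant mock c (adjusted p up to 0.151), with the stricter filter (0.0531) and with both mock libraries nearest the Pst side left out (0.589).

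Beside these 5 lower and 0 higher genes, edgeR gave 378 genes higher and 265 lower in mutant mock at an unadjusted p under 0.05. That is a smaller share of the 19680 genes tested than the 0.05 expected by chance, so it shows no excess of differences. DESeq2 called 4 higher and 12 lower and limma voom 0 higher and 5 lower. Without mutant mock a the count was 99, of which 89 were higher and 10 lower, without Col-0 mock 1 it was 8 with 1 higher, and the call of AT1G21670 ended without mutant mock b (adjusted p = 0.152) and with only the groups compared (0.0761), in a range from 1.14e-10 to 0.152 over the alternatives.

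The fourth comparison asked how infected leaves differed between the genotypes. After Pst, photosynthesis genes were higher and proteasome subunits lower in nac53-1 78-1 than in Col-0. Of the light reaction genes, 46 of 47 were higher, with a median log2 difference of 2.32, and CAB2, a chlorophyll a/b-binding protein, was 10.1-fold higher at 1877 ± 654 against 186 ± 45.5 CPM, with estimates that may include reads of similar loci. Of the proteasome subunits, 36 of 38 were lower, with a median of -1.28, and PBB2 was 6.62-fold lower at 25.4 ± 2.53 against 168 ± 9.88 CPM. Between the genotypes, 4865 genes differed (24.7%), 3642 higher and 1223 lower in the mutant, and 2496 of the higher and 159 of the lower ones at least 2-fold.

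Proteasome genes of infected mutant leaves stood apart in both parts of the complex. Counts were the same when adjusted over the list alone, with 36 lower (camera adjusted p = 2.16e-35, and adjusted p = 0.186 with an estimated correlation). The core subunit PAE1 was 5.28-fold lower, at 15.8 ± 2.05 against 83.4 ± 4.46 CPM, and RPT5B was 6.56-fold lower. AT5G20000, written as RPT6B in the list and left out of it because the reference gives no such symbol, was 6.78-fold lower, with fractional estimates in all 13 libraries. In the list of activators, CDC48 and ubiquitin, 4 of 10 were lower and 5 when adjusted over the list alone (camera adjusted p = 0.000924, and adjusted p = 0.396 with an estimated correlation), with the proteasome activator PA200 2.34-fold lower at 199 ± 25.9 against 466 ± 54.1 CPM. Autophagy genes had 4 of 20 lower (median -0.50, camera adjusted p = 2.08e-05, and adjusted p = 0.396 with an estimated correlation). AT2G48160 was 476-fold lower after Pst as well (adjusted p = 1.57e-08), and MRD1, at 7.26 ± 1.18 CPM in Col-0 Pst, had 0 counts in the mutant Pst libraries.

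The lists of photosynthesis, glucosinolates and endoplasmic reticulum chaperones were higher in infected mutant leaves. The light reaction genes (camera adjusted p = 2.08e-37, and adjusted p = 0.186 with an estimated correlation) included PETE1, 9.32-fold higher at 37.6 ± 9.65 against 4.06 ± 1.00 CPM. Of the Calvin cycle genes, 17 of 19 were higher, and 18 when adjusted over the list alone (median 2.26, camera adjusted p = 2.36e-16, and adjusted p = 0.186 with an estimated correlation). The phosphoribulokinase PRK was 7.76-fold and HCEF1 6.01-fold higher. Chlorophyll genes were higher in 17 of 21 cases, and 20 when adjusted over the list alone (median 1.66, camera adjusted p = 6.76e-13, and adjusted p = 0.236 with an estimated correlation). GUN5, a subunit of magnesium chelatase, was 8.66-fold higher at 900 ± 254 against 104 ± 35.3 CPM. Of the aliphatic glucosinolate genes, 14 of 17 were higher (median 2.46, camera adjusted p = 9.89e-09, and adjusted p = 0.396 with an estimated correlation), MAM1 by 9.2-fold. Endoplasmic reticulum chaperones were higher in 11 of 16 cases, and 13 were higher and 1 lower when adjusted over the list alone (median 1.22, camera adjusted p = 5.63e-05, and adjusted p = 0.396 with an estimated correlation), with the calreticulin CRT1b 4.17-fold and the chaperone SHD 3.29-fold higher. In the list of camalexin and indole glucosinolates, 5 of 17 were higher (median 0.29, camera adjusted p = 0.0294, and adjusted p = 0.593 with an estimated correlation). MYB34, a regulator of indole glucosinolates, was 5.42-fold higher, and the tryptophan-oxidising enzyme CYP79B3 was 3.54-fold higher at 243 ± 70.0 against 68.7 ± 14.6 CPM. The indole list call ended without Col-0 Pst a (adjusted p = 0.0581), without mutant Pst b (adjusted p = 0.0639) and with the stricter filter on low counts (adjusted p = 0.0551).

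The jasmonate, salicylic acid, pattern-triggered immunity and ethylene lists had 2 to 4 called members each between the genotypes after Pst. Jasmonate genes were higher in the mutant in 3 of 30 cases, also when adjusted over the list alone (camera adjusted p = 0.531). Salicylic acid genes were higher in 3 and lower in 1 of 27, and in 2 and 1 when adjusted over the list alone (camera adjusted p = 0.531), with a median that changed sign under another scaling. In the pattern-triggered immunity list 1 was higher and 2 were lower of 28, and 0 either way when adjusted over the list alone (median -0.32, camera adjusted p = 0.0248, and adjusted p = 0.597 with an estimated correlation, 0.258 with fry), a call that ended without Col-0 Pst 1 (adjusted p = 0.122). Ethylene genes had 2 of 22 lower, and 1 when adjusted over the list alone (median -0.18, camera adjusted p = 0.0463, and adjusted p = 0.597 with an estimated correlation, 0.279 with fry). EBF1, which targets ethylene regulators for degradation, was 1.49-fold lower (adjusted p = 0.00303), and the list call ended without Col-0 Pst 1 (adjusted p = 0.145) and without mutant Pst a (adjusted p = 0.246), as well as with RLE factors (0.0534), with no filter on low counts (0.0622) and with fractional loci left out (0.06).

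Single genes with large differences after Pst included AT1G13650 (58.3-fold higher in the mutant), AT2G10940 (51.5-fold) and ELP, an extensin-like protein (31.2-fold). PR1 was at 132 ± 66.3 CPM in the mutant and 81.5 ± 21.3 CPM in Col-0 (adjusted p = 0.372), EDS16 at 568 ± 91.3 and 873 ± 141 CPM (adjusted p = 0.254, and 0.0443 to 0.506 over the alternatives, the former with only the groups compared) and FRK1 at 13.5 ± 3.66 and 17.3 ± 5.01 CPM (adjusted p = 0.378). The share of higher genes among those called was 74.9%, and 91.2% with library totals in place of TMM factors, where 412 genes were lower. The count of 4865 was 2569 without mutant Pst a, 3031 without Col-0 Pst a and 3094 without Col-0 Pst 2, the count of higher genes was 2236 without mutant Pst a, and the count of lower genes was 333, 362 and 436 in the same 3 refits, 717 without mutant Pst c and 785 without Col-0 mock 2.

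**Figure D4:**
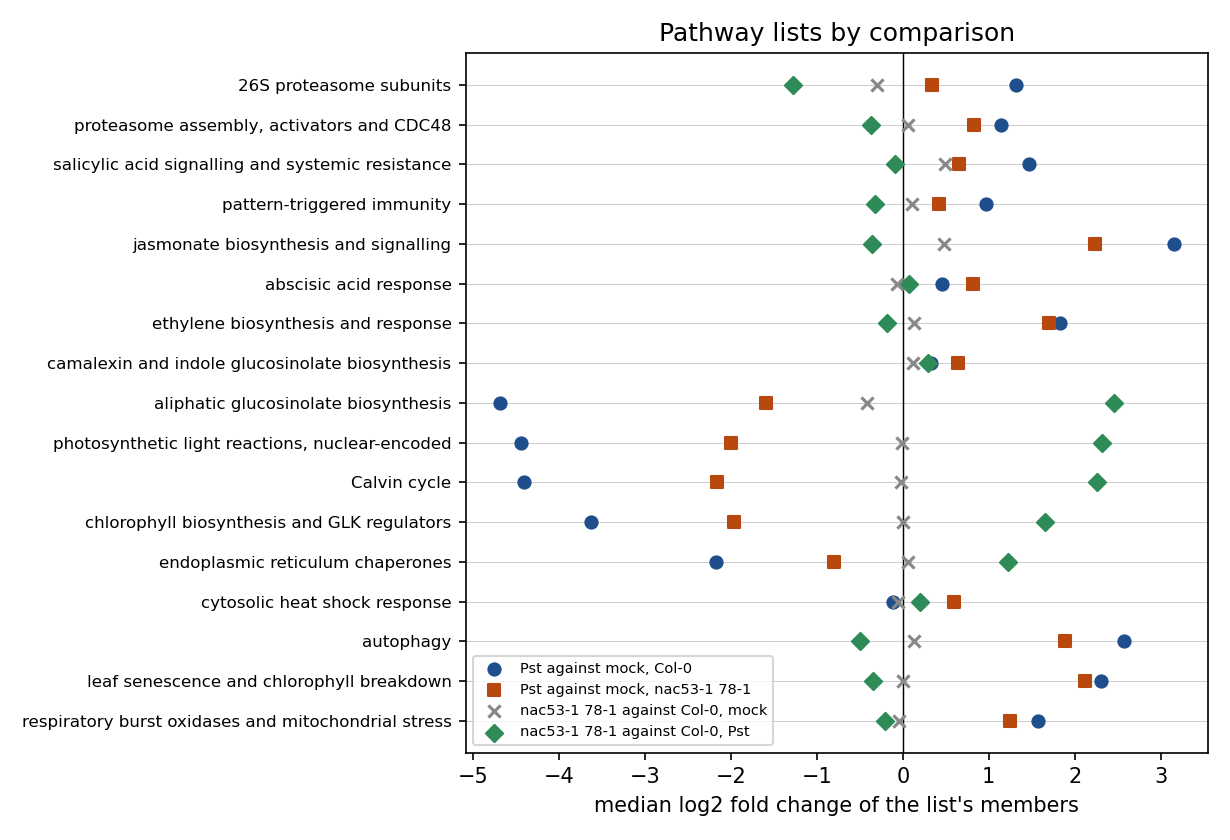
Each symbol is the median log2 fold change (x axis) of the members used of 1 of the 17 pathway lists (y axis) in 1 of 4 comparisons. Proteasome subunits lie at 1.32 for Pst in Col-0, 0.35 for Pst in the mutant and -1.28 between the genotypes after Pst, and the light reaction genes lie at -4.44, -2.00 and 2.32; in mock, the sign of the light reaction and chlorophyll medians turned with the scaling, as did that of salicylic acid after Pst.

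The interaction asked whether the response to Pst itself differed between the genotypes. The response was smaller in the mutant for 99.5% of the 2353 genes with an interaction, and for 92% of all genes called in the Col-0 response. The interaction was positive for 2101 genes, of which 2093 fell in Col-0, and negative for 252, of which 249 rose in Col-0. Light reaction genes had a median interaction of 2.44, with 43 of 47 positive and 46 when adjusted over the list alone, and proteasome subunits one of -0.93, with 32 of 38 negative and 37 when adjusted over the list alone. Among genes that changed in Col-0, the median ratio of the mutant to the Col-0 log2 response was 0.665. These genes, like the 2353, were called with the Col-0 libraries that also give the Col-0 response. That choice by itself favours a smaller response in the mutant, so these shares and the ratio may overstate it.

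For the proteasome list the call was camera adjusted p = 3.43e-29, and adjusted p = 0.258 with an estimated correlation. PAE1 (log2 -1.67, SE 0.21, adjusted p = 0.00163) and PBB2 (log2 -1.77, SE 0.23, adjusted p = 0.00163) had the smallest p of the list. PAE1 rose 2.77-fold in Col-0, from 30.1 ± 5.88 to 83.4 ± 4.46 CPM, and was at 18.16 ± 0.886 and 15.8 ± 2.05 CPM in the mutant. Positive interactions were called in 14 of 19 Calvin cycle genes, 16 when adjusted over the list alone (camera adjusted p = 2.01e-13, and adjusted p = 0.288 with an estimated correlation), with PRK at 3.06. Of 21 chlorophyll genes, 14 had one, 16 when adjusted over the list alone (camera adjusted p = 1.09e-10, and adjusted p = 0.378 with an estimated correlation), with GUN5 at 3.05 and CRD1 at 2.42. The light reaction genes (camera adjusted p = 1.23e-32, and adjusted p = 0.258 with an estimated correlation) included PETE1 at 3.11. Aliphatic glucosinolates had 14 of 17 positive, 16 when adjusted over the list alone (median 2.99, camera adjusted p = 8.02e-11, and adjusted p = 0.378 with an estimated correlation), with MAM1 at 3.61. Outside the lists, the positive interactions included the latex-protein homologue MLP423 at 6.44 (2 counts in the Col-0 Pst libraries, which allow 4.85 to 9.75) and AT1G13650 at 6.32, and the negative ones the argonaute AGO3 at -2.82, AT1G52315 at -2.18 and AT5G58300 at -2.01. AT1G79210, written as PAB2 in the proteasome list and left out of it, had -1.87.

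The interaction count was 1324 without mutant Pst a and 4607 without mutant mock a. The count of 2101 positive interactions was 1245 and 3203 in these refits. The count of 252 negative interactions was 79 and 1404 in them, 666 without Col-0 Pst 1, 93 without Col-0 Pst 2, 81 without Col-0 Pst a, 131, 111 and 112 without Col-0 mock 1, 2 and 3, 142 without mutant Pst c, and 136 and 93 without mutant mock b and c.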

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

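Of the tests below, those of the smaller response, of the proteasome subunits, of adjacent genes and of shared reads were chosen only after the result was seen; the counts of other splits were not.

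The response to Pst differed between the genotypes by a test of the interaction itself, with 2353 genes called, 2101 positive and 252 negative. Lists with a median interaction past the camera threshold were the 26S proteasome subunits (-0.928), proteasome activators with CDC48 and ubiquitin (-0.482), salicylic acid (-0.737), pattern-triggered immunity (-0.443), ethylene (-0.428), autophagy (-0.631), aliphatic glucosinolates (2.99), light reactions (2.44), Calvin cycle (2.26), chlorophyll synthesis (1.67), endoplasmic reticulum chaperones (1.24) and epidermis markers (0.851). The calls of the proteasome activators (adjusted p = 0.111) and of the endoplasmic reticulum chaperones (0.0825) ended with fractional loci left out. With an estimated correlation the adjusted p of these lists lay between 0.258 and 0.698, past no threshold. With fry, 5 of the 12 calls passed the threshold and 7 did not (adjusted p from 0.0991 to 0.583), which were the proteasome activators, salicylic acid, pattern-triggered immunity, ethylene, autophagy, the chaperones and the epidermis markers. The call of salicylic acid ended without mutant mock c (adjusted p = 0.0798), Col-0 Pst 1 (0.0558) and mutant Pst a (0.0659). That of ethylene ended without mutant mock c (adjusted p = 0.101), Col-0 Pst 1 (0.0619), Col-0 mock 1 (0.0677) and mutant Pst a (0.0648). That of the epidermis markers ended without Col-0 Pst a (adjusted p = 0.0928), mutant Pst a (0.0595) and mutant mock b (0.0608).

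Named genes with an interaction of large positive size were MLP423 (6.44), AT1G13650 (6.32), AT2G10940 (5.91), AT1G67750 (5.45), ELP (5.44), LHCB2.3 (5.41), EXPA5 (5.39) and AT4G01460 (4.91). In Col-0 Pst, MLP423 had 2 counts and AT1G67750 3, which allow an interaction of 4.85 to 9.75 and of 4.06 to 7.89, so their place among these genes is open. The call of AT1G67750 ended without Col-0 Pst a (adjusted p = 0.0844), Col-0 Pst 1 (0.0524) and mutant Pst a (0.0724), and with limma voom (0.0976), as did that of EXPA5 (0.0547). LHCB2.3 had fractional estimates. Large negative values were those of AGO3 (-2.82), AT2G32130 (-2.57), AT1G52315 (-2.18), AT5G54040 (-2.18), AT5G58300 (-2.01), AT2G14290 (-1.93), AT1G79210 (-1.87) and AT5G02170 (-1.79). With 1 library left out, the adjusted p of AT2G32130 ranged from 0.00407 to 0.21 and passed 0.05 without Col-0 Pst 2 and a, Col-0 mock 1 to 3, mutant Pst a and b, and mutant mock b and c. The adjusted p of AT2G14290 passed 0.05 without the same libraries, in a range from 0.00387 to 0.138. That of AT5G54040 ranged from 0.00139 to 0.245 and stayed under 0.05 only without mutant mock a. These 3 calls also ended with limma voom (adjusted p = 0.0895 for AT2G32130, 0.092 for AT2G14290 and 0.143 for AT5G54040) and, with that of AT5G02170 (0.0734), with both mock libraries nearest the Pst side left out (0.128, 0.0617 and 0.307). With library totals those of AT2G32130 (0.0522) and AT5G54040 (0.058) ended, and with no filter that of AT2G32130 (0.0586).

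Named list members with an interaction were PAE1 (-1.67), PBB2 (-1.77), PA200 (-1.01), EFR (0.94), ERF1 (-1.20), ATG6 (-0.492), IMD1 (3.19), MAM1 (3.61), PETE1 (3.11), CAB2 (3.28), PRK (3.06), FBA1 (3.30), CRD1 (2.42), GUN5 (3.05), CRT1b (1.99) and CRT1a (1.55). The call of PA200 ended without Col-0 Pst 2 and a, mutant Pst a and c, and mutant mock c (adjusted p up to 0.06). That of CRT1a ended without mutant Pst a (adjusted p = 0.0546) and with both mock libraries nearest the Pst side left out (0.0567). That of EFR ended in 10 of 13 refits, all but those without Col-0 Pst 1, mutant Pst c or mutant mock a (adjusted p up to 0.122). That of ERF1 ended in 10, all but those without Col-0 mock 4, mutant Pst b or mutant mock a (adjusted p up to 0.104). That of ATG6 ended in 11, all but those without Col-0 mock 4 or mutant mock a (adjusted p up to 0.126). The calls of EFR (adjusted p = 0.144), ERF1 (0.0748) and ATG6 (0.0771) also ended with both mock libraries nearest the Pst side left out. Other settings that ended them were RLE factors (0.0618) and organelle loci left out (0.0506) for EFR, limma voom (0.058), no filter (0.0508) and library totals (0.0538) for ERF1. For ATG6 they were upper quartile factors (0.06), no filter (0.109), organelle loci left out (0.0574), library totals (0.187) and fractional loci left out (0.0776).

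Some Col-0 mock libraries stood apart from the other 3 by Dixon's ratio for 13 of 113 values. In 4 of these the other 3 libraries were at 0, where any count stands apart, and without values of that kind it was 9 of 107, where 5% are reached by chance. In Col-0 mock 4 these were PP2-B7 (0.08 CPM), UBQ4 (55.2 CPM), HCEF1 (713.99 CPM), PR1 (111.5 CPM, others 21.67 to 35.66), GH9B15 (0.24 CPM), AT3G04190 (0.32 CPM), LOX4 (46.59 CPM), RPT5B (29.69 CPM) and PA200 (314.37 CPM). In Col-0 mock 1 they were CYP79F2 (29.13 CPM) and MYB34 (26.02 CPM), and in Col-0 mock 2 CKX2 (0.04 CPM) and RHD2 (5.96 CPM).

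Other splits of the libraries were refitted for each count. The real split of the Col-0 libraries, with 15997 genes, was 1 of 35 and the highest other gave 9743. Its share lies under 0.05 and is the smallest that 35 splits can give, so chance was argued against at that level only. Splits cannot address samples that are partly technical replicates. For the mutant response, 13588 genes against 0 in the highest other split, and for the genotypes after Pst, 4865 against 0, the 10 splits are too few for a share under 0.05. For the genotypes in mock, 4 of 35 splits gave at least 5 genes, so chance was not excluded for that count. The highest other gave 902, and what sets its libraries apart was not tested. For the interaction, 6 of 100 splits drawn gave at least 2353 genes, with 4303 in the highest other. All 6, the real split among them, were among the 9 drawn that keep the genotypes apart in Pst. The other 91 gave at most 1 gene. The 9 retain the real difference after Pst, so this share cannot tell chance from a real interaction. Chance was thus not excluded by it.

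The smaller response of the mutant, with a slope of 0.689, was weighed first. Scaling of the libraries as its cause was argued against, since a factor per library shifts every interaction alike. The 1018 genes that fell at least 4-fold in the mutant had a median interaction of 1.73 and the 2140 that rose had one of -0.54, a difference of at least 1.78 with any 1 library left out. A single library was argued against too, since the slope without any 1 library was at most 0.779. For the genes that fell, a share of tissue in the mutant Pst samples not reached by the bacterium may be the cause. So may tissue not yet responding. The 555 genes that fell at least 16-fold in Col-0 kept typically 22.69% of their mock level in the mutant (29%, 20.6% and 18.1% in mutant Pst a, b and c). Of them, 0.36% lay more than 2-fold below this typical share, beyond their error. That bound was set from the same genes, so it shows only that they kept similar shares (quartiles 19.03% and 26.03%). The genes that rose cannot decide whether a mixture with such tissue is the whole cause. They were chosen by their rise in Col-0, and the Col-0 Pst level also enters the difference. That choice can by itself lower the difference. The 335 that rose at least 16-fold in Col-0 had a median log2 difference between the genotypes after Pst of -0.58 where the mixture predicts -0.37, which is -0.207 from it. This distance was -0.397, -0.107 and -0.201 in mutant Pst a, b and c, and with library totals it was 0.0143 in mutant Pst b. A mixture of mutant mock and Col-0 Pst RNA had a median absolute residual of 0.137 over 11121 genes, and the slope one of 0.241. The former is a residual of the mutant Pst level and does not use the Col-0 mock libraries. The latter is one of a log2 fold change and carries the spread of all 4 groups. They are thus unlike measures and cannot rank the mixture against a weaker response. A weaker or later response of every cell because of the genotype stays open too, untested, and bacterial numbers were not analysed here.

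The lower level of proteasome subunits after Pst was weighed next. The overall smaller response was argued against as its whole cause, because the subunits had a median mutant response of 0.345 where random lists of genes with the same Col-0 response had 0.849 to 1.06. Leaving such a range was common, as 8 of the other 16 pathway lists did, 7 above and 1 below. All 38 subunits lay below their matched genes, by a median log2 of -0.60 that was -0.69 to -0.54 with 1 library left out. The subunits vary together (estimated correlation 0.608), so they are not 38 independent results. Other lists shifted steadily too, aliphatic glucosinolates by 0.623 (0.522 to 0.724) and endoplasmic reticulum chaperones by 0.474 (0.255 to 0.68). Salicylic acid genes shifted by -0.377 (-0.67 to -0.145), with 23 of 27 below. The downward shift of the subunits was the largest of the pathway lists. A mixture with mock tissue was argued against as well, as the subunits lay at a median of -1.08 from the level it predicts, 21 of 38 more than 2-fold below it. Reads shared between paralogous subunits were argued against by the 24 subunits with whole estimates, all lower, at a median of -1.31. A dependence of these genes on NAC53 and NAC78 in infected leaves is a hypothesis that remains, found and tested on the same data, and these libraries cannot show whether it is direct.

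The near absence of AT2G48160 and MRD1 in the mutant was weighed last. A test written before the result, the median log2 difference in mock over the 10 nearest tested genes (-0.0278 for AT2G48160 and -0.155 for MRD1), cannot see a deletion of a few genes and was replaced by the level of the adjacent genes. A deletion that takes in a neighbouring gene may be the cause for AT2G48160: AT2G48150, the only tested gene next to it, had 75 counts over the 7 Col-0 libraries and 1 over the 6 mutant libraries, which leaves 1.41% of the Col-0 level (counting interval 0.0352% to 8.1%). These counts are few, and the next tested gene, AT2G48130, kept 87.8%. For MRD1 the loss of a whole neighbouring gene was argued against, since the tested genes next to it kept 33.4% (HEI10, interval 27% to 41.1%) and 184% (MSL4), with counts in each mutant library. HEI10 overlaps MRD1 and was lower after Pst (log2 -2.09, SE 0.32, adjusted p = 0.00078), so a loss that reaches into part of it stays open. Shared reads were argued against by estimates that were whole for both genes, with 0 libraries not whole. A change within each gene, such as a variant or an insertion carried by the line, was not tested and may be a cause, and no biological explanation beyond the genotype was tested.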

How the results depend on the processing

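The settings with library totals, with fractional loci left out, with list members as written and with 1 mock library of each genotype left out were chosen after seeing the data; the others were planned.

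Of the counts recomputed, 338 stayed within 1.5 times the reported value and 52 moved further. For named genes, 4060 values kept their direction and side of the threshold, 37 passed it only under the alternative, 137 lost it and 0 changed direction while called. For lists, 1491 calls kept both, 157 lost the threshold, 66 of them with an estimated correlation and 21 with fry, and 5 reversed. With fry, which tests a list by itself and not against other genes, 0 of the 10 list calls between the genotypes in mock passed the threshold (adjusted p from 0.447 to 0.966). After Pst 12 of 16 did, for the interaction 5 of 12, and for the responses 15 of 15 in Col-0 and 13 of 13 in the mutant. Most genes changed in the responses, so passing fry says little there. Some lists passed fry without a camera call. In Col-0 these were abscisic acid (fry adjusted p = 0.0053, camera adjusted p = 0.309), guard cell (0.00393 and 0.273), phloem (0.00393 and 0.406) and dividing cell markers (0.00165 and 0.169). In the mutant they were pattern-triggered immunity, abscisic acid, indole glucosinolates, guard cell and phloem markers (fry adjusted p from 0.00576 to 0.0155, camera adjusted p from 0.096 to 0.34). The slope was recomputed only with each of 13 libraries left out and for genes with a mean of at least 10 CPM (0.670). These 14 values lay within 1 jackknife SE (0.096) of the reported slope. That SE was computed from the same 13 refits, so this is no independent check. Other methods, scalings and filters were not run for the slope.

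Between the genotypes in mock, DESeq2 called 16 genes, 4 higher and 12 lower. After Pst the count of lower genes was 2052 with DESeq2, 643 with no filter on low counts, 712 with fractional loci left out and 412 with library totals. A fold of 1.5 tested with glmTreat gave 1804 genes (1724 higher, 80 lower), and an adjusted p under 0.01 gave 2252 (2022 higher, 230 lower). For the interaction the count of negative genes was 804 with DESeq2, 148 with no filter, 102 with library totals and 110 with Col-0 mock 4 and mutant mock c left out. The fold of 1.5 gave 1086 genes (1066 positive, 20 negative), and an adjusted p under 0.01 gave 837 (803 positive, 34 negative). The stricter thresholds lower counts by construction; for the other settings the cause was not tested.

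With each library left out in turn, the Col-0 response had 15345 to 16232 genes and the mutant response 12303 to 13827. The genotypes in mock gave 4 to 99 genes (0 to 89 higher, 4 to 10 lower), where limma voom gave 5. At an unadjusted p under 0.05, edgeR with all libraries gave 643 of 19680 genes, a smaller share than the 0.05 expected by chance. The genotypes after Pst gave 2569 to 5602 genes (2236 to 3950 higher, 333 to 1652 lower). The interaction gave 1324 to 4607 (1245 to 3203 positive, 79 to 1404 negative). In these last 3 comparisons the highest values were those without mutant mock a, and for the genotypes after Pst and the interaction the lowest were those without mutant Pst a; the cause was not tested.

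Reversed camera directions of called lists were found between the genotypes in mock, where the call was lost as well. Camera sets a list against the other genes, and the list medians were not computed in these refits. For pattern-triggered immunity the adjusted p was 0.14 without mutant mock c, 0.000535 to 0.151 over the libraries left out, and 0.589 with both mock libraries left out. For jasmonate it was 0.351 without mutant mock b and 0.977 without mutant mock c, in a range from 1.21e-29 to 0.977. For dividing cell markers it was 0.992 without mutant mock a, in a range from 1.81e-05 to 0.992. The cause was not tested.

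Median shifts over all genes above 0.1 came from upper quartile factors (-0.215 in Col-0, -0.193 in the mutant) and from library totals (0.108 between genotypes after Pst, 0.116 for the interaction). List medians that changed sign under a scaling were those of xylem markers in the mutant response, light reactions and chlorophyll synthesis between genotypes in mock, salicylic acid after Pst, and guard cell and phloem markers in the interaction.

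A replicate block was possible for the Col-0 response with numbers 1 and 2, and called 15829 genes with 98% of those reported. No paired analysis was possible for the other comparisons because the columns carry no replicate number. In simulated data, where few genes were changed, 5.97% of 2-fold interactions were recovered. The share for data with 2353 interactions called was not simulated. A missing interaction call below a 2-fold size is therefore not read as absence.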

Other observations

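The comparison of photosynthesis genes with matched genes was chosen only after the result was seen, and so were the single genes named in this part, after their values.

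Epidermis markers fell in both responses, 8 of 8 in Col-0 (median -2.77, camera adjusted p = 0.00475, and adjusted p = 0.507 with an estimated correlation) and 7 of 8 in the mutant (median -2.02, camera adjusted p = 0.00917, and adjusted p = 0.657 with an estimated correlation). PDF2 (AT4G04890), a homeodomain regulator of the epidermis, was at 55.1 ± 8.65 CPM in Col-0 mock and 3.00 ± 1.17 CPM in Col-0 Pst. Guard cell markers rose in 5 of 8 and fell in 2 in Col-0 (camera adjusted p = 0.273), with the potassium channel KAT1 at 42.3 ± 4.01 and 162 ± 37.6 CPM. Phloem markers rose in 4 of 8 and fell in 1 in Col-0 (camera adjusted p = 0.406), with the sugar exporter SWEET12 at 8.85 ± 5.53 and 91.6 ± 15.4 CPM and the sulfate transporter SULTR2;1 at 117 ± 16.5 and 9.18 ± 1.98 CPM. Xylem markers fell in 2 of 8 in Col-0 (camera adjusted p = 0.494) and were higher in the mutant after Pst in 6 of 8, and 8 when adjusted over the list alone (median 0.76, camera adjusted p = 0.00143, and adjusted p = 0.396 with an estimated correlation). Dividing cell markers rose in 1 of 8 and fell in 6 in Col-0 (camera adjusted p = 0.169) and were higher in the mutant after Pst in 5 of 8 (median 1.31, camera adjusted p = 0.0265, and adjusted p = 0.396 with an estimated correlation). The dividing cell call ended with fractional loci left out (adjusted p = 0.06). Between the genotypes after Pst, epidermis markers were higher in 2 of 8 (median 0.71, camera adjusted p = 0.0451, and adjusted p = 0.597 with an estimated correlation, 0.113 with fry) and guard cell markers lower in 2 of 8 (median -0.48, camera adjusted p = 0.0376, and adjusted p = 0.486 with an estimated correlation, 0.0866 with fry). The epidermis call ended without Col-0 Pst a (adjusted p = 0.234) and mutant Pst a (0.127), with the stricter filter (0.079), with library totals (0.0607) and with fractional loci left out (0.0564). The guard cell call ended without Col-0 Pst 2 (adjusted p = 0.0746), Col-0 Pst a (0.0892) and mutant Pst b (0.074). Except for the xylem list, these counts were the same when adjusted over the list alone.

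Clock genes rose in 8 of 12 and fell in 2 in Col-0 (median 1.70, camera adjusted p = 0.0398, and adjusted p = 0.507 with an estimated correlation). The evening complex genes ELF3 and ELF4 were at 4.42 ± 1.11 and 0.32 ± 0.0926 CPM in Col-0 mock and at 162 ± 24.3 and 9.42 ± 1.65 CPM after Pst, and PRR5 at 1.5 ± 0.899 and 123 ± 17.8 CPM. In the mutant, clock genes rose in 7 of 12 and fell in 2, and 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.533 with an estimated correlation), and ELF3 went from 4.88 ± 1.94 to 97.8 ± 9.75 CPM. The Col-0 call ended with the stricter filter (adjusted p = 0.066), with fractional loci left out (0.129), with only the groups compared (0.053) and with both mock libraries nearest the Pst side left out (0.0517). The mutant call ended with fractional loci left out (adjusted p = 0.0628). Between the genotypes after Pst, 2 of 12 were lower (median -0.36, camera adjusted p = 0.00526, and adjusted p = 0.22 with an estimated correlation), a call that ended with fractional loci left out (adjusted p = 0.06). The labels give no hour of the day.

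Abscisic acid genes rose in 9 of 19 and fell in 4 in Col-0, 8 and 4 when adjusted over the list alone (camera adjusted p = 0.309), and rose in 7 and fell in 3 in the mutant (camera adjusted p = 0.141). NCED3, of abscisic acid synthesis, was at 14 ± 3.92 CPM in Col-0 mock and 170 ± 36.2 CPM after Pst, and the phosphatase HAI1 at 25.6 ± 14.7 and 503 ± 61.9 CPM. Heat shock genes rose in 3 of 15 and fell in 2 in Col-0, 2 and 0 when adjusted over the list alone (camera adjusted p = 0.689), with a median of -0.11 and a mean of 0.22 that differ in sign. The indole glucosinolate genes rose in 8 of 17 and fell in 5 in Col-0 (camera adjusted p = 0.495), where the regulator MYB34 fell 4.69-fold from 18.3 ± 5.19 to 3.92 ± 3.10 CPM, against 14.6 ± 3.53 and 21.1 ± 6.37 CPM in the mutant. Respiratory burst and mitochondrial stress genes rose in 7 of 12 in the mutant (camera adjusted p = 0.0281, and adjusted p = 0.666 with an estimated correlation), a call that ended without mutant mock b (adjusted p = 0.0527).

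It was asked whether photosynthesis genes were spared in the mutant beyond its smaller response. The light reaction genes had a median mutant response of -2.00, and random lists of genes with the same Col-0 response had -2.18 to -1.93, so the smaller response may account for it. A first matching, also on the mock level, was replaced because its genes had a median Col-0 response of -3.45 in place of -4.44. It gave -1.95 to -1.68 for the light reactions and 0.783 to 1.05 for the proteasome subunits.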
